A study of Rattus norvegicus with 21 samples.

How the data were processed

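Gene expression was measured on Affymetrix rat arrays in 21 tissue samples from 9 male young adult Fischer 344 rats. Per the labels, BDEneu tumours and the normal right liver lobe were taken from 3 rats each at days 10, 15 and 25 after inoculation, and a peritoneal metastasis was also taken from each of the 3 rats of day 25. This gave 7 groups of 3 arrays, 1 per rat and tissue, and the replicates of a group were different rats. The description of each day 25 liver sample names day 55, whereas its title and source name day 25; day 25 was used. The labels give no scan date or processing batch, so batch effects between arrays were not analysed here. Tissue was snap-frozen, and biotin-labelled cRNA was made from total RNA, per the labels' protocols.

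The deposited values are log2 expression per probe set, made by the authors with RMA (background correction, quantile normalization across arrays and a summary over the probes of a probe set), per the submitters' processing notes. The program and version behind RMA are not given in the sources used here. The table held 31099 probe sets, 57 of them array controls, with values from 3.16 to 14.62 on the log2 scale. Array medians lay between 5.98 and 6.06. Because RMA aligns the distribution of every array, a change that shifted most transcripts in 1 direction would be partly removed, and levels of very abundant transcripts such as Alb lie near the top of the scale, where differences are compressed. No detection calls came with the values, so levels under the array medians were not parted into signal and background. Changes from or to levels near either end of the scale are given as measured; their exact size and their order are not to be relied on. Arrays carry no read depth; the number of arrays per group limits the precision, and the median SD of a gene between the 3 rats of a group ran from 0.11 (day 10 tumours) to 0.177 (day 25 livers) on the log2 scale.

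Gene names came from the platform annotation given with the data. It names a single gene symbol for 20832 probe sets and several symbols for 436; 9831 probe sets are not listed there and were not named. Symbols were updated through the gene identifier in a current rat gene table (assembly GRCr8, used for names only), which held the identifier of 20764 of the single-symbol probe sets. No coordinates are given because the genome build behind the array annotation is not given in the sources used here. Each gene was represented by the single-symbol probe set with the highest mean over all arrays, which left 14218 genes, 4526 of them with more than 1 probe set. Probe sets of several symbols were left out.

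Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, prior without a trend). The model held all 21 arrays as 7 group means with 1 shared estimate of the spread per gene, and p-values were adjusted by the Benjamini-Hochberg method over the 14218 genes. A gene was called at an adjusted p under 0.05. All changes are given as log2 fold changes with their standard error (SE). The 11 comparisons were tumour against liver over all days and at each day, the 3 pairs of tumour days, metastasis against day 25 tumour and against day 25 liver, liver at day 25 against day 10, and the change of the tumour-liver difference from day 10 to day 25 (interaction).

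In addition, 27 gene lists were tested as groups with camera (inter-gene correlation preset at 0.01, adjusted over the lists of a comparison). They cover hepatocyte function, bile ducts, ErbB signalling, cell division, connective tissue, hypoxia, immune cells, vessels and other tissues that the samples could hold. Of their 510 members, 453 were measured, 9 of the members after matching an older symbol to the current one. Camera was also run with the correlation estimated from the data, which is a much stricter test for co-regulated lists. Counts of list members refer to the adjustment over all genes unless given as adjusted over the list alone.

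The groups, the comparisons, the tests, the 27 lists and the rule for naming genes were fixed before the data were examined. For tumour against liver over all days, tumour day 25 against day 10, metastasis against tumour and liver day 25 against day 10, the rule named up to 10 genes per direction with the largest change among called genes whose arrays did not overlap between the groups, leaving out provisional names. From each list described it named up to 3 called members with the largest change and 1 uncalled member with the highest mean. Erbb2 was named in every comparison. In the other comparisons only list members and genes already named were used. With 3 arrays against 3, chance alone separates 10% of all genes without overlap. Among called genes the arrays did not overlap for 4573 genes in tumour against liver over all days, 8 in tumour day 25 against day 10, 48 in metastasis against tumour and 1267 in liver day 25 against day 10.

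The tissues of 1 rat are paired by the rat numbers in the labels. The deviations of 2 tissues of the same rat from their group means correlated with r between 0.04 and 0.3 over genes, except for tumour and metastasis of rat 7 (r of 0.58). Genes are not independent replicates, and these values only describe the arrays. The fit with the rat as a fixed block was run as an alternative, as was the rat as a random block (consensus correlation of 0.136).

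Alternatives fixed at the same time were a prior with an intensity trend, quantile normalization on top of the deposited values, centring each array on its median, leaving out the dimmer genes, testing every probe set, the mean of the probe sets of a gene, fitting only the groups compared, an adjusted p under 0.01, a minimum change of 2-fold, both rat blocks, and leaving out each array in turn. Leaving out rat 7, leaving out 3 arrays with pancreatic transcripts, a hepatocyte score as covariate, and the list tests without each array in turn were chosen after seeing the data. Further gene lists used in the closing section were also chosen after seeing the data.

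The test steps were tested on simulated data, in which 50 genes per size were changed among 14218 genes. At a log2 change of 1, 92% of changed genes were recovered for tumour against liver over all days, 80% for tumour day 25 against day 10, 84% for metastasis against tumour, 78% for liver day 25 against day 10 and 54% for the interaction. At a log2 change of 0.5 these shares were 72%, 40%, 32%, 32% and 14%. With no simulated effect, 0 genes were called in each of these comparisons by limma. In the runs with changed genes, 2 to 10 unchanged genes were called. The simulated noise was independent between genes and had the same spread in all groups. In the data genes vary together and the day 25 groups spread more, so these shares may be too high for day 25 comparisons.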

Results

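The series followed the growth of an intrahepatic cholangiocarcinoma, a cancer of the bile ducts inside the liver, in the rat. BDEneu cells are rat cholangiocytes, the cells that line bile ducts, transformed with an activated neu (Erbb2) oncogene, which encodes a receptor tyrosine kinase. Tumours of 3 rats were profiled at each of days 10, 15 and 25 after inoculation, with the right liver lobe of each of the 9 rats and a peritoneal metastasis of each day 25 rat. Array medians differed little, between 5.98 and 6.06 on the log2 scale. The mean correlation of an array with the others of its group ran from 0.959 (day 25 tumour, replicate 1, from rat 7) to 0.994. The tumour and metastasis of rat 7 were nearly alike, with r of 0.993 over all probe sets. Pairs of day 25 tumours had r of 0.951 to 0.989 and pairs of metastases 0.956 to 0.979. The first principal component held 74.3% of the variance, with liver arrays between 47.7 and 88.8 and tumour and metastasis arrays between -93.6 and -13.8.

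Erbb2, the transforming gene of the cell line, was measured first as a check of the labels. Its log2 level was 9.18 ± 0.32 (SD, n = 3) in day 10 tumours, 9.26 ± 0.68 at day 15, 10.03 ± 0.69 at day 25 and 10.12 ± 0.66 in metastases, against 5.43 ± 0.17, 5.28 ± 0.25 and 5.30 ± 0.36 in the liver at days 10, 15 and 25.

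Tumour pieces also carried liver transcripts. The median signal of 18 hepatocyte genes, as a percentage of that in the liver of the same rat, was 40.5, 21.7 and 36% in the day 10 tumours, 19.8, 47.7 and 14.4% at day 15, 2.96, 29.3 and 31.7% at day 25, and under 1% in each metastasis (0.574, 0.95 and 0.494%). In the metastases 8 of the 18 genes had means under the lowest array median, and in the day 25 liver 5 had means within 1 log2 of the highest value, so these percentages are set partly by the ends of the scale and are no measure of liver content. Transcripts of the exocrine pancreas lay more than 1 log2 above the median array in 3 arrays, whose means over 9 acinar genes were 8.46, 8.4 and 10.87. Day 10 tumour replicate 2 was next at 6.41. The remaining tumour and metastasis arrays had means of 5.31 to 5.57. The log2 level of Prss1, which encodes trypsinogen, was 9.01 in day 15 tumour replicate 2, 8.32 in day 25 tumour replicate 3 and 11.42 in metastasis replicate 2. In the other 9 tumour and metastasis arrays it lay between 4.48 and 6.11.

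The comparison of tumour with liver asked which transcripts set the growing tumour apart from the organ around it. Bile duct and connective tissue genes led the increases (n = 9 tumours and 9 livers). Krt19 and Krt7, keratins of bile duct epithelium, were higher by 6.31 (SE 0.26, adjusted p = 3.3e-12) and 6.04 (SE 0.18, adjusted p = 8.9e-14) on the log2 scale, and Krt20, a keratin of gut-type epithelium, by 5.79 (SE 0.18). Postn, the matricellular protein periostin, rose by 8.05 (SE 0.35, adjusted p = 6e-12), from 4.94 ± 1.02 in liver to 12.99 ± 0.26 in tumour (SD). The matrix genes Tnc (tenascin C, 6.52, SE 0.34), Lum (lumican, 6.28, SE 0.48) and Mfap5 (6.04, SE 0.24), the epithelial lectin gene Lgals4 (6.58, SE 0.17), the tetraspanin gene Tspan8 (6.40, SE 0.21) and the laminin chain gene Lamb3 (5.76, SE 0.13) were the other genes named by size of increase. Of these 10 genes 8 had liver means below the lowest array median, so the sizes and order of these changes are limited by the bottom of the scale. Erbb2 rose by 4.16 (SE 0.22, adjusted p = 5.8e-11).

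The 10 genes named by size of decrease encode enzymes and transporters of the liver. Cyp4a1, a fatty acid hydroxylase, fell by 3.99 (SE 0.47, adjusted p = 9.5e-07). Aass (-3.73), Tat (-3.70), Dmgdh (-3.64), Ftcd (-3.63) and Hgd (-3.55) fell too, with SEs from 0.36 to 0.44. Bbox1, which makes carnitine, changed by -3.68 (SE 0.39), and Sult2a6, a sulfotransferase of steroids and bile acids, by -3.55 (SE 0.36). The canalicular export pumps Abcc2 and Abcb11, which move conjugates and bile salts into bile, changed by -3.62 (SE 0.35) and -3.61 (SE 0.45).

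By list, 17 of 19 biliary epithelium genes rose and 0 fell (median 2.54), with Cd24 at 5.54 and the keratin gene Krt18 uncalled at -0.10. Of 25 myofibroblast and collagen genes, 24 rose and 1 fell (median 3.02). All 29 cell cycle genes rose (median 1.63), led by the replication licensing gene Mcm6 (3.04), the cyclin gene Ccna2 (2.84) and the cytokinesis gene Ect2 (2.62). Among 22 matrix proteases and inhibitors, 17 rose and 2 fell (median 1.31), with the macrophage elastase gene Mmp12 at 4.60, the inhibitor gene Timp1 at 4.09 and Adam8 at 4.05 (-0.25 by its other probe set). Among 19 TGF-beta and mesenchymal genes 16 rose and 1 fell (median 1.53), with Ccn2 (connective tissue growth factor) at 4.29 and Cdh11 at 4.28 (-0.18 and 0.21 by its other probe sets). Of 21 hypoxia and glycolysis genes 16 rose and 0 fell (median 1.15), with Egln3 at 4.58, Ndrg1 at 3.14 and Car9 at 2.92. Camera called these 6 lists as higher (adjusted p = 4e-07, 3.2e-08, 4e-07, 3e-05, 0.00012 and 0.00018). With an estimated correlation they gave adjusted p = 0.39 or 0.4.

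On the side of liver function all 20 bile acid and drug handling genes fell (median -2.92), among them Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 3.45. Of 18 hepatocyte genes 17 fell (median -2.18), including Tat, Otc (-3.35) and Hpd (-2.88), whereas albumin, Alb, was uncalled at -0.43 (adjusted p = 0.2). Of 15 fatty acid oxidation genes 13 fell (14 adjusted over the list alone, median -1.68), with Ehhadh at -3.18, and of 14 cholesterol synthesis genes 10 fell (median -0.71), with Nsdhl at -2.06. Markers of liver sinusoid endothelium fell in 7 of 9 cases and rose in 1 (median -1.31), with the scavenger receptor gene Stab2 at -2.72 and Dnase1l3 at -2.17. Of 7 red blood cell genes 6 fell, all by small amounts (median -0.32). Camera called these 6 lists as lower (adjusted p = 4.8e-06, 0.00024, 5.1e-05, 0.022, 0.017 and 0.042), and with an estimated correlation adjusted p = 0.39 to 0.48. The red blood cell list lost its call after quantile normalization (adjusted p = 0.076) and without tumour day 15 replicate 3, tumour day 25 replicate 3 or liver day 25 replicate 1 (0.052, 0.051 and 0.053). The tumours held the liver signal given above. Liver RNA mixed into the pieces, if present, would make the decrease of a liver gene smaller than in tumour cells alone.

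Myeloid cell genes were higher in tumours. Of 19 macrophage genes 15 rose and 2 fell (median 0.95), with the lysozyme gene Lyz2 at 2.73 and Gpnmb at 2.30, while Clec4f, a marker of the resident Kupffer cells of the liver, fell by 2.85. Of 9 neutrophil genes 8 rose and 1 fell (median 2.19), with Csf3r and Il1r2 both at 3.12 and Il1b at 2.64. Camera called both lists as higher (adjusted p = 0.00086 and 0.0023; with an estimated correlation adjusted p = 0.4 and 0.39), and likewise the immediate early list (12 of 16 rose, 2 fell, adjusted p = 0.045; adjusted p = 0.4 with an estimated correlation), with Myc at 2.01. The immediate early call rested on several arrays. It ended (adjusted p = 0.051, 0.06, 0.057, 0.053, 0.057 and 0.08) without tumour day 10 replicate 1, day 15 replicate 3 or day 25 replicate 2, or liver day 10 replicate 3, day 15 replicate 2 or day 25 replicate 2. Chemokine genes rose in 11 of 22 cases and fell in 4 (median 1.05, camera adjusted p = 0.08; 0.048, called, without tumour day 25 replicate 1). Cxcl6 and Cxcl2, attractants of neutrophils, were at 4.86 and 3.88 and Ccl2, an attractant of monocytes, at 4.85. The 3 probe sets of Cxcl12 disagreed in sign (0.27, -0.39 and -0.66).

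The ErbB list went both ways, with 7 of 17 genes higher and 8 lower (median 0.07, camera adjusted p = 0.83); Ptgs2 (cyclooxygenase 2) rose by 3.24 and the ligand gene Areg by 2.85. Of 20 T and NK cell genes 7 rose and 2 fell (camera adjusted p = 0.36), with Cd8a at 1.36 (0.01 by another probe set) and Gzma at -1.03. Of 21 interferon response genes 2 rose and 12 fell (adjusted p = 0.15), with Gbp2 at 2.73 and Mx2 at -1.29 (-0.24 by its other probe set). Acute phase genes rose in 4 of 19 cases and fell in 9 (adjusted p = 0.26), with A2m at 1.79 and Crp at -2.05. Further uncalled lists were B and plasma cell (2 higher and 4 lower of 10, adjusted p = 0.66, median 0, mean 0.17 and test direction down), blood vessel endothelium (8 and 2 of 13, 0.12; 0.05 with the rat as a block and 0.048 without tumour day 25 replicate 1, both calling it), circadian clock (2 and 10 of 15, 0.094; 0.048 with the rat as a block, which called it), adipocyte (4 and 8 of 14, 0.19), smooth and skeletal muscle (5 and 1 of 15, 0.54), peritoneal mesothelium (3 and 2 of 9, 0.86, median -0.02 and mean 0.54) and pancreatic acinar and intestinal epithelium (2 and 2 of 16, 0.66).

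**Figure D1:**
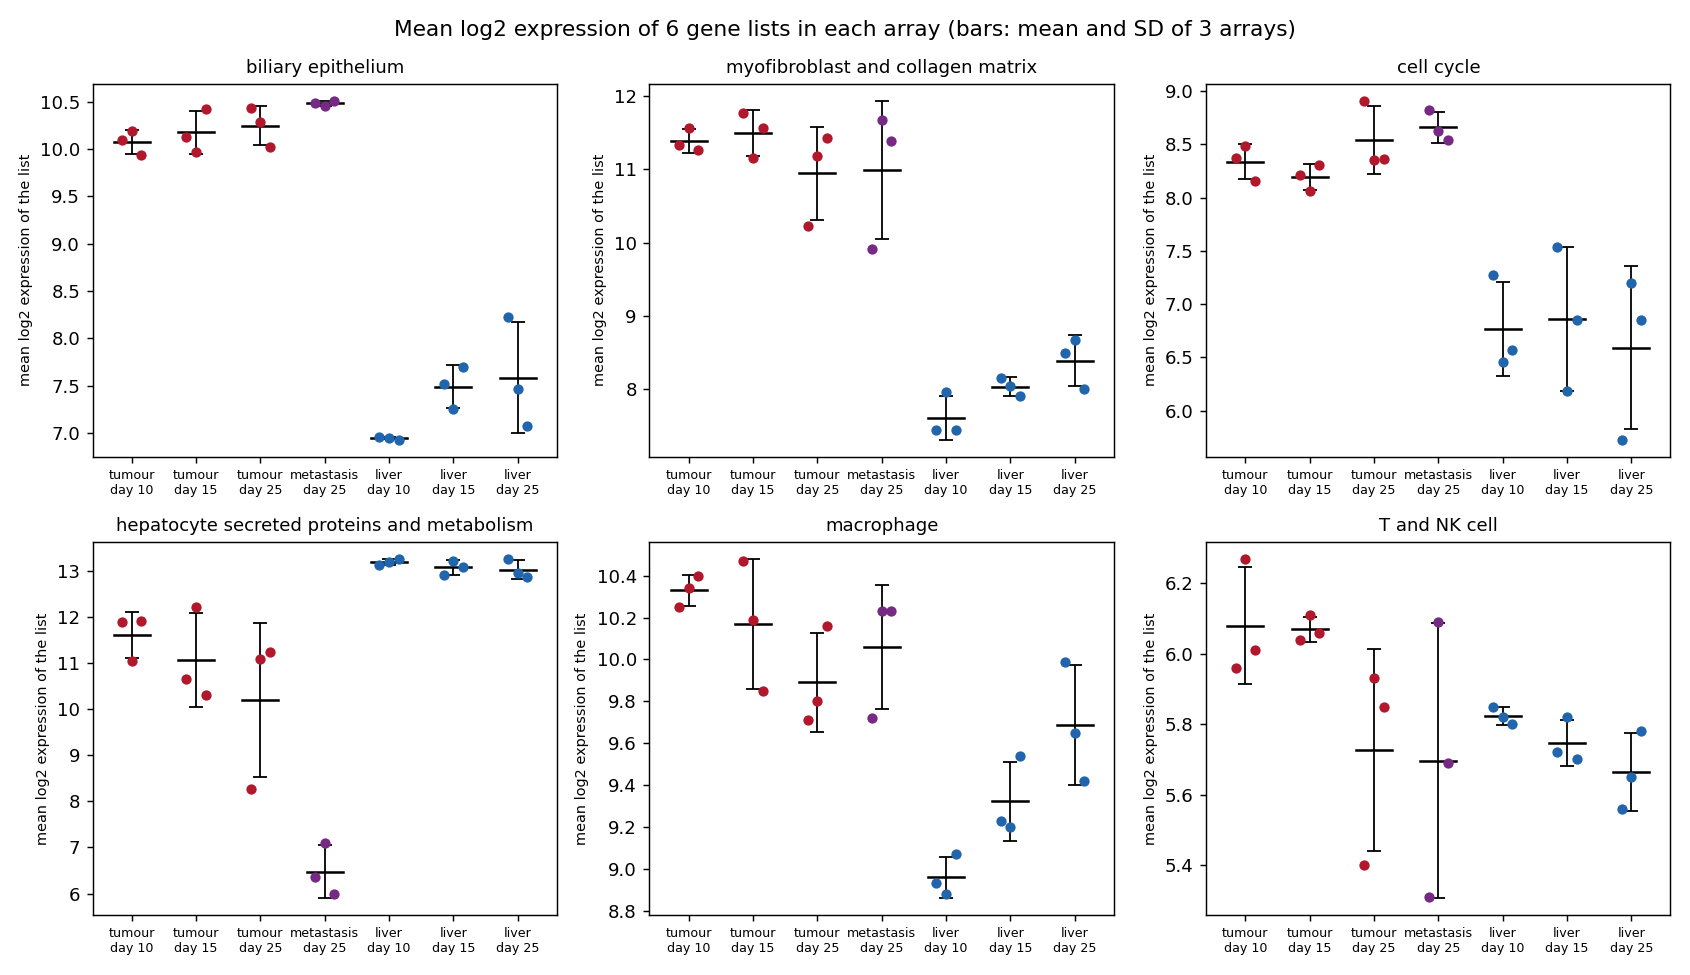
Mean log2 expression (vertical axis) of 6 gene lists in each array, by group (horizontal axis); points are arrays and bars show the mean and SD of 3 arrays. The biliary list lay between 9.94 and 10.51 in tumours and metastases and at most at 8.22 in livers, and the hepatocyte list between 5.98 and 7.1 in metastases.

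In total limma called 10606 of 14218 genes, 5229 higher and 5377 lower, in tumour against liver over all days, and 2994 of them by at least 2-fold (1808 higher, 1186 lower). At single days, each with 3 tumours and 3 livers, the counts were 8306 (4318 higher, 3988 lower), 7364 (4009, 3355) and 7124 (3938, 3186) for days 10, 15 and 25. Krt19 was higher by 6.86, 6.16 and 5.91 (SE 0.45), Postn by 8.26, 7.72 and 8.17 (SE 0.60), and Erbb2 by 3.76, 3.98 and 4.73 (SE 0.37). At all 3 days, which used different rats, 3023 genes were higher and 2060 lower, with 1 gene differing in direction. Independent lists of these sizes would share 337 and 211. The days compare the same 2 tissues and share 1 estimate of the spread per gene, so the excess over these numbers is no separate support. Macrophage genes rose in 16, 14 and 6 of 19 cases at days 10, 15 and 25 (medians 1.52, 1.15 and 0.17), and 2 fell at each day. The list was called at days 10 and 15 (camera adjusted p = 9.9e-06 and 0.00043, and 0.41 at both days with an estimated correlation) and not at day 25 (adjusted p = 0.28). At day 25 the mean of the macrophage list differed between tumour and liver by -0.28 in rat 7, 0.15 in rat 8 and 0.74 in rat 9. Acute phase genes fell in 0, 0 and 10 of 19 cases, with the list called as lower at day 25 (median -1.53, adjusted p = 0.0079; adjusted p = 0.48 with an estimated correlation). This call rested on the tumour of rat 7. The mean of the list differed between tumour and liver by -3.27 in rat 7, -0.63 in rat 8 and -0.51 in rat 9. Without tumour day 25 replicate 1 the list was uncalled (median -0.66, adjusted p = 0.058). Differences between the days were tested as an interaction.

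Within the tumours, the comparison of days asked what changed as they grew. From day 10 to day 25 limma called 8 of 14218 genes, 2 higher and 6 lower (n = 3 and 3). Cndp1, a dipeptidase of carnosine, rose by 3.45 (SE 0.56, adjusted p = 0.026), from 8.77 ± 0.20 to 12.21 ± 0.66 (SD), and Pgbd5, a transposase-derived gene, by 1.55 (SE 0.27, adjusted p = 0.049), which lost its call after quantile normalization and after median centring. Clec9a, a receptor of cross-presenting dendritic cells, fell by 1.52 (SE 0.22, adjusted p = 0.011), the chemokine gene Ccl17 by 1.25 (SE 0.18, adjusted p = 0.011), the germinal centre gene Gcsam by 1.15 (adjusted p = 0.031) and the lymphocyte receptor gene P2ry10 by 0.72 (adjusted p = 0.026). Ch25h, cholesterol 25-hydroxylase of activated myeloid cells, fell by 1.65 (SE 0.23, adjusted p = 0.011). The remaining gene carries a provisional name. Each of the 7 named genes lost its call without day 10 tumour replicate 2 or 3 or day 25 tumour replicate 1 or 2, and Cndp1 and Pgbd5 also without day 10 tumour replicate 1 (adjusted p = 0.0817 to 0.275). In those fits the 7 genes kept most of their size. The rule named only genes whose arrays did not overlap between the days, so their direction could not turn. Cndp1 was at 3.1 to 3.54 and Pgbd5 at 1.26 to 1.74. Clec9a was at -1.54 to -1.38, Ccl17 at -1.19 to -1.12 and Ch25h at -1.62 to -1.47. Gcsam was at -1.17 to -1 and P2ry10 at -0.76 to -0.61. Erbb2 was uncalled at 0.85 (SE 0.37, adjusted p = 0.26).

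No list member was called over all genes from day 10 to day 25, while camera called 13 of the 27 lists, 3 higher and 10 lower. The members named below were thus uncalled. Under the rule for naming genes, only the uncalled member with the highest mean of each list was fixed in advance. For the hypoxia list that was Pgk1, at 0.30. The higher lists were hypoxia and glycolysis (21 genes, median 0.42, adjusted p = 4.9e-05), with Adm at 1.66, Slc2a3 at 1.42 and Car9 at 1.24, ErbB (17 genes, median 0.30, adjusted p = 0.032; 2 higher adjusted over the list alone), with Areg at 2.14 and Egfr at -1.08, and cell cycle (29 genes, median 0.19, adjusted p = 0.04). The lower lists included T and NK cell (20 genes, median -0.37, adjusted p = 8.9e-06; 8 lower adjusted over the list alone), with Cd3d at -0.76 and Lck at -0.68, interferon response (21 genes, median -0.55, adjusted p = 7.3e-05; 6 lower adjusted over the list alone), with Mx1 at -1.31, Isg15 at -1.15 and Rsad2 at 1.61, and macrophage (19 genes, median -0.35, adjusted p = 9.5e-05), with Adgre1 at -1.13. Bile acid and drug handling (median -1.59, adjusted p = 6.3e-07; 9 lower adjusted over the list alone), hepatocyte (median -1.39, adjusted p = 8.9e-06) and acute phase genes (median -0.98, adjusted p = 0.032) were lower too. The hepatocyte signal of the day 25 pieces lay outside the day 10 range in rat 7 alone. The other lower lists were myofibroblast and collagen (median -0.43, adjusted p = 0.012), blood vessel endothelium (-0.56, 0.015), TGF-beta (-0.50, 0.04; 0.0509 after quantile normalization, which ended its call) and sinusoid endothelium (-0.23, 0.04). With an estimated correlation all 13 gave adjusted p = 0.52 to 0.72.

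Many of these list calls rested on the tumour of rat 7, day 25 replicate 1. Without it the hepatocyte (median -0.28), acute phase (0.13), cell cycle (-0.02), myofibroblast (-0.05), blood vessel (-0.14), TGF-beta (-0.17) and sinusoid (-0.14) lists were uncalled (adjusted p = 0.062, 0.091, 0.48, 0.84, 0.61, 0.42 and 0.24). The bile acid list was then at -0.77. The acute phase, TGF-beta and sinusoid lists were also uncalled without tumour day 10 replicate 1 (0.1, 0.084 and 0.099). The acute phase, cell cycle and sinusoid lists were uncalled without day 10 replicate 3 (0.11, 0.17 and 0.11). The ErbB list was uncalled without day 25 replicate 2 (0.18), where the cell cycle median was 0.30. Without day 25 replicate 3 the medians were -2.10 for the hepatocyte, -1.58 for the acute phase, -0.67 for the myofibroblast, -0.86 for the blood vessel and 0.68 for the hypoxia list. The hypoxia, bile acid, T and NK cell, interferon and macrophage lists were called without any 1 array. The T and NK cell median was -0.25 without day 10 replicate 2. The median of the matrix protease list was -0.04 with a mean of 0.08 and a test direction of up (adjusted p = 0.51), and the adipocyte list had a median of 0.14 and a mean of -0.18 (0.49), with 0.18 and -0.01 for the muscle list (0.88).

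At an unadjusted p under 0.05 limma gave 2444 genes for day 25 against day 10. In each comparison of 14218 genes 711 would pass this limit by chance if no gene differed. The count of 8 depended on which arrays were used. The kept direction of the named genes without 1 array was set by the naming rule and is no check of the count. The count was 0 without tumour day 10 replicate 2 or 3 or without tumour day 25 replicate 1 or 2, 159 without tumour day 25 replicate 3, 1156 without the 3 arrays with pancreatic transcripts, and 0 with the hepatocyte score as a covariate. Between day 10 and day 15 limma called 0 genes (350 at an unadjusted p under 0.05) and between day 15 and day 25 0 genes (1202). Without tumour day 15 replicate 3 these counts were 1 and 7, and with every probe set 0 and 1; the other settings gave 0. From day 10 to day 15 Erbb2 differed by 0.07 (SE 0.37, adjusted p = 0.999) and the hypoxia list was higher (median 0.42, camera adjusted p = 3.1e-08; adjusted p = 0.41 with an estimated correlation; median 0.20 without tumour day 15 replicate 3). From day 15 to day 25 Erbb2 differed by 0.77 (SE 0.37, adjusted p = 0.606), the interferon list was lower (median -0.68, adjusted p = 6.7e-09; adjusted p = 0.23 with an estimated correlation) and the T and NK cell list as well (median -0.31, adjusted p = 8e-07; adjusted p = 0.48 with an estimated correlation). The interferon median was -0.44 without tumour day 15 replicate 2, and the T and NK cell median -0.13 and -0.49 without tumour day 25 replicates 1 and 2.

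Metastases were compared with the day 25 tumours of the same rats (n = 3 and 3). The limma adjusted p given here come from the fit without the rat as a block. With the block all 13 named called genes lost their call. Of the 47 genes that fell 20 belong to the hepatocyte or acute phase lists, and those named here include plasma proteins made by the liver. Fga, Fgb and Fgg, the chains of fibrinogen, changed by -6.73 (SE 0.65, adjusted p = 0.00019), -6.45 (SE 0.79, adjusted p = 0.0007) and -6.42 (SE 0.65, adjusted p = 0.00019). Orm1, an acute phase glycoprotein, was at -6.46 (SE 0.73, adjusted p = 0.0003). The inter-alpha-trypsin inhibitor genes Itih3 (-6.04) and Itih4 (-5.90), the protease inhibitor genes Pzp (-6.08), Serpinc1 (-5.86) and Serpina1 (-5.47), the fetuin gene Ahsg (-5.86), prothrombin, F2 (-5.51), and the drug-metabolising Cyp2c6v1 (-6.19) also fell, with adjusted p from 0.00024 to 0.0048. Fgb was at -0.05 and -0.13 by 2 other, dimmer probe sets. The metastasis means of 35 of the 47 genes lay under the lowest array median, among them Cyp2c6v1 (4.15), Serpinc1 (4.58), F2 (4.67) and Ahsg (5.18), so the sizes and order of these changes are limited by the bottom of the scale. The only called increase was that of Armc10 (0.42, SE 0.08, adjusted p = 0.03), which lost its call after quantile normalization. Erbb2 differed by 0.09 (SE 0.37, adjusted p = 0.97).

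Of 18 hepatocyte genes 9 fell (14 adjusted over the list alone, median -4.36, camera adjusted p = 1.7e-47; adjusted p = 0.0047 with an estimated correlation), and of 19 acute phase genes 11 fell (14 adjusted over the list alone, median -4.45, adjusted p = 1.7e-47; adjusted p = 0.0028 with an estimated correlation). Ttr (-3.53, adjusted p = 0.067) and Cp (-2.85, adjusted p = 0.145) were uncalled. Bile acid and drug handling genes (20 genes, 0 called and 9 lower adjusted over the list alone, median -1.62, adjusted p = 2.1e-18) and fatty acid oxidation genes (15 genes, 0 called, median -0.18, adjusted p = 0.0004) were also called as lists, with adjusted p = 0.1 and 0.69 with an estimated correlation. The fatty acid oxidation call ended without tumour replicate 2 or 3 or metastasis replicate 1 (adjusted p = 0.061, 0.061 and 0.083). Its median was -0.48 and -0.42 without tumour replicate 1 and metastasis replicate 2. The hepatocyte signal was under 1% of that of the own liver in each metastasis and up to 31.7% in the day 25 tumours. No other list was called, but 12 of the uncalled lists were called without 1 array: the myofibroblast, macrophage, T and NK cell, B cell, blood vessel, sinusoid, adipocyte, hypoxia, pancreatic, red blood cell, TGF-beta and muscle lists. The biliary list had a median of 0.28 (adjusted p = 0.23; 0.0069 with the rat as a block, which called it as higher), with Krt8 at 0.21, and the macrophage list 0.25 (adjusted p = 0.11; 0.043 with the rat as a block, which called it as higher). Cell cycle genes had a median of 0.12 (adjusted p = 0.96) and the myofibroblast list 0.04 (adjusted p = 0.65, with a mean of 0.05 and a test direction of down). Without tumour replicate 1 or metastasis replicate 2 the myofibroblast list was called as lower (medians -0.39 and -0.31, adjusted p = 0.0034 and 0.0011) and without metastasis replicate 1 as higher (0.54, 4.5e-05). The macrophage list was called as higher without tumour replicate 3 or metastasis replicate 1 (0.0013 and 0.00048). Median, mean and test direction also differed in sign for the uncalled protease, B cell, chemokine, interferon, mesothelium, muscle and immediate early lists.

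**Figure D2:**
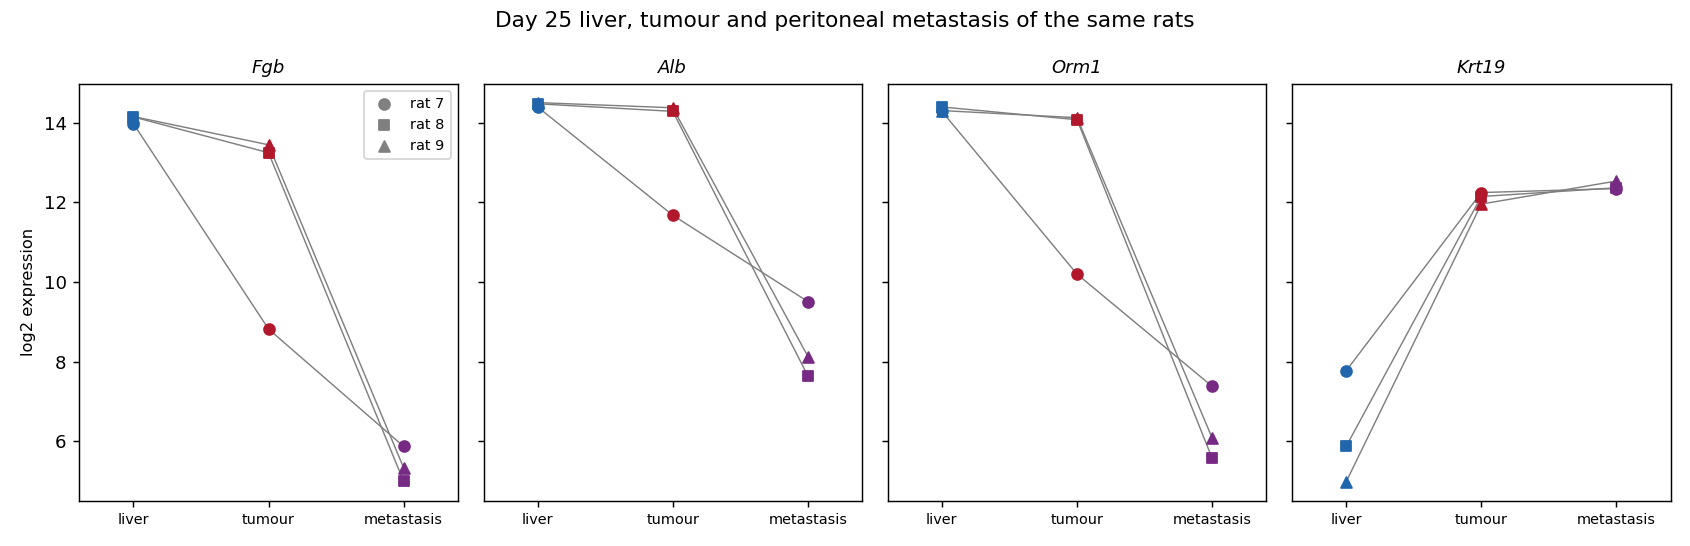
Log2 expression (vertical axis) of Fgb, Alb, Orm1 and Krt19 in liver, tumour and metastasis (horizontal axis) of rats 7, 8 and 9 at day 25; each point is 1 array and lines join the arrays of a rat. Fgb was at 8.82, 13.25 and 13.45 in the tumours of rats 7, 8 and 9 and at 5.87, 4.99 and 5.33 in their metastases.

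Limma called 48 of 14218 genes in metastasis against tumour, 1 higher and 47 lower. At an unadjusted p under 0.05 it gave 863, where 711 would pass by chance if no gene differed. With the rat as a block it called 0 genes (1212 at an unadjusted p under 0.05), with only the groups compared 1, and 0 with the hepatocyte score as a covariate. The score lay between 5.98 and 7.1 in the metastases and at 8.28, 11.1 and 11.25 in the tumours. It parts the groups by itself, so the fit with it is no check of these calls. The tumour of rat 7, day 25 replicate 1, held least liver signal (2.96%): without it 220 genes were called and without all arrays of rat 7 187. The count was 21 and 25 without tumour replicates 2 and 3, 25 without metastasis replicate 3 and 19 without the 3 arrays with pancreatic transcripts.

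Against the day 25 liver, the metastases showed bile duct, matrix and cell cycle genes as higher, like the primary tumours, and liver transcripts as far lower. Some liver transcripts, such as Hp (8.49), A2m (8.43) and Alb (8.42), still lay above the array medians in the metastases. Krt19 was higher by 6.21 (SE 0.45, adjusted p = 1.8e-08), Postn by 7.81 (SE 0.60, adjusted p = 3.6e-08) and Erbb2 by 4.82 (SE 0.37, adjusted p = 3.8e-08). Alb fell by 6.04 (SE 0.52, adjusted p = 1.2e-07) and Fgb by 8.70 (SE 0.79, adjusted p = 1.9e-07). Both levels in liver (14.46 and 14.10) lay near the top of the scale and that of Fgb in metastases (5.40) under the array medians, so these sizes are not exact. All 18 hepatocyte genes fell (median -6.76), as did 18 of 20 bile acid genes (median -5.16), 16 of 19 acute phase genes (1 rose, median -5.96) and 7 of 9 sinusoid endothelium genes (median -1.54). All 29 cell cycle genes rose (median 2.05), with 14 of 19 biliary genes (1 fell, median 3.02) and 20 of 25 myofibroblast genes (1 fell, median 2.38). Camera called these 7 lists (adjusted p = 2.2e-11, 2.4e-09, 1.4e-08, 0.0013, 1.9e-07, 1e-06 and 2.4e-05; with an estimated correlation adjusted p = 0.31 to 0.46) and 11 in all. Limma called 8103 genes, 4742 higher and 3361 lower.

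The right liver lobe, labelled as normal tissue, also changed between day 10 and day 25 (n = 3 and 3). Obp3, an odorant-binding protein gene, changed by -5.96 (SE 1.48, adjusted p = 0.019), Cyp2c11, the main male-specific cytochrome P450 of rat liver, by -5.54 (SE 1.32, adjusted p = 0.016), from 13.48 ± 0.12 to 7.94 ± 2.79 (SD), and the urinary protein gene Mup5 by -4.08 (adjusted p = 0.036; -2.62 and -1.09 by its other, dimmer probe sets). The carboxylesterase gene Ces1d (-5.84, SE 0.84, adjusted p = 0.00072), the carbonic anhydrase gene Car3 (-5.66, adjusted p = 0.034), Dhrs7l1 (-5.36), the lipid droplet gene Pnpla3 (-4.68, adjusted p = 0.0046), Stac3 (-4.52), Nrep (-3.95) and the desaturase gene Scd (-3.34, SE 0.94, adjusted p = 0.036) were the other large decreases.

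Acute phase and neutrophil genes led the increases. A2m, alpha-2-macroglobulin, a main acute phase protein of the rat, rose by 5.26 (SE 0.64, adjusted p = 0.00022), from 7.87 ± 0.89 to 13.13 ± 0.29 (SD). Lcn2 (lipocalin 2) rose by 4.89 (SE 0.83, adjusted p = 0.0027), S100a8 and S100a9, the calprotectin chains of neutrophils, by 4.44 (SE 0.68) and 3.50 (SE 0.48), and the decoy receptor gene Il1r2 by 3.67 (SE 0.33, adjusted p = 2.3e-05). Fst (follistatin, 3.88), the guanylate cyclase gene Gucy2c (3.49), the elastase inhibitor gene Serpinb1a (3.44; 1.00 by its other probe set), the fatty acid binding gene Fabp4 (2.95) and the chemokine gene Ccl21 (2.90) were also higher. Erbb2 was uncalled at -0.13 (SE 0.37, adjusted p = 0.88).

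**Figure D3:**
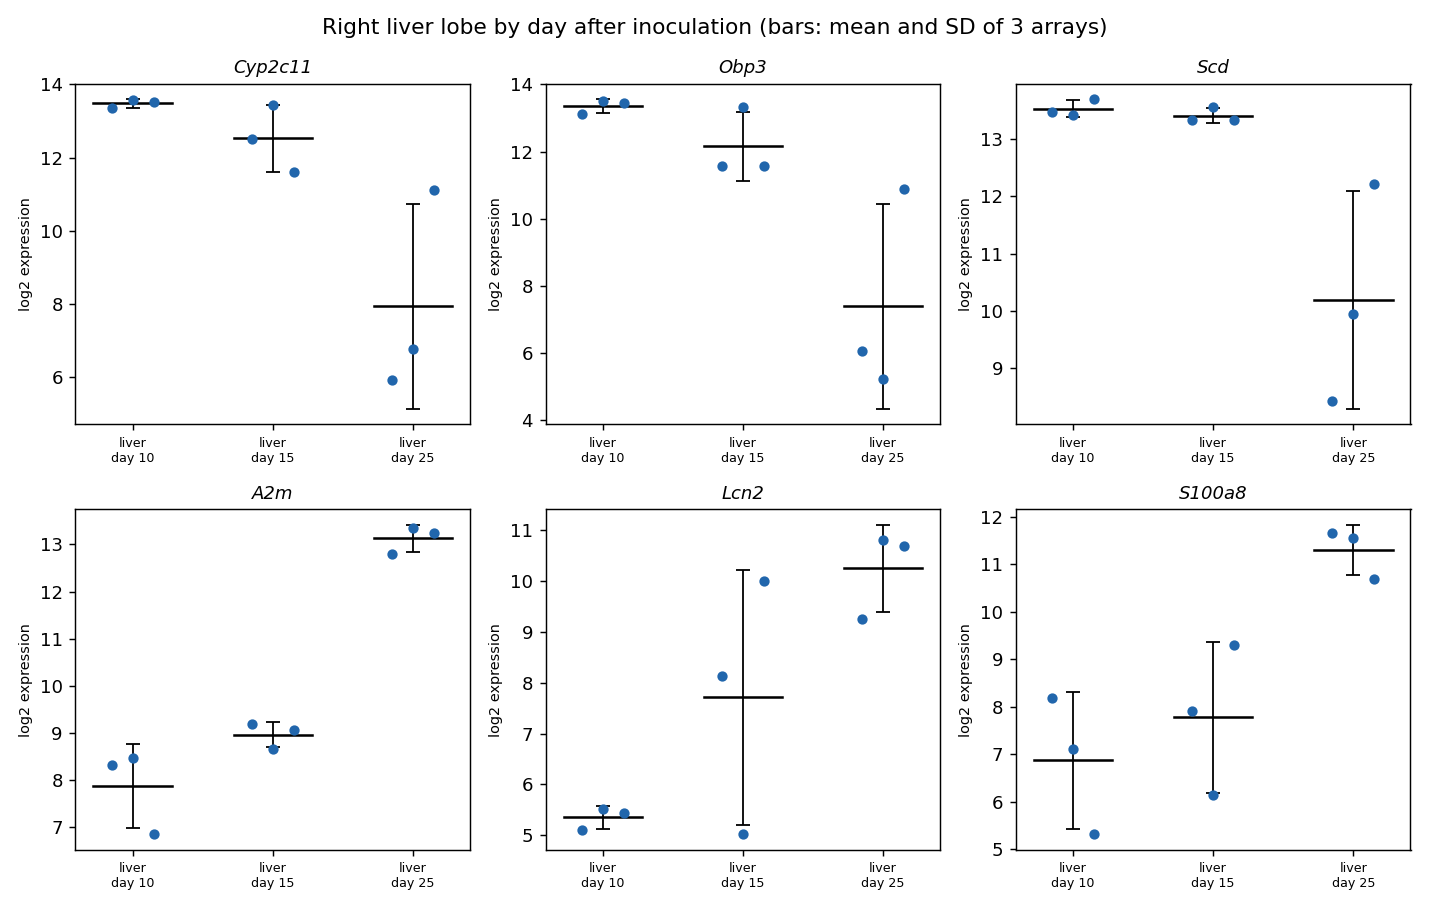
Log2 expression (vertical axis) of Cyp2c11, Obp3, Scd, A2m, Lcn2 and S100a8 in the right liver lobe at days 10, 15 and 25 (horizontal axis); points are arrays and bars show the mean and SD of 3 arrays. Cyp2c11 was at 5.93, 6.76 and 11.13 in the 3 day 25 livers and A2m at 12.8, 13.34 and 13.24.

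By list, 12 of 19 macrophage genes rose in the liver and 0 fell (14 higher adjusted over the list alone, median 0.77), with the lysosomal protease gene Lgmn at 1.39 (0.20 by its other probe set), Gpnmb at 1.25 and the haemoglobin scavenger receptor gene Cd163 at 1.20. Of 9 neutrophil genes 5 rose and 0 fell (median 0.82). Of 22 matrix proteases and inhibitors 7 rose and 0 fell (9 higher adjusted over the list alone, median 0.52). The 3 members named by size were the inhibitor genes Timp1 (1.73), Timp3 (1.16) and Timp2 (0.94). The protease gene Plau rose as well, by 0.93 (limma adjusted p = 0.0066). Of 25 myofibroblast and collagen genes 5 rose and 0 fell (median 0.80), with Dcn at 2.34, Lox at 1.90 and Col1a2 at 1.42 (uncalled after quantile normalization and with the mean of its probe sets). Of 19 biliary genes 4 rose and 0 fell (median 0.33), with Cd24 at 1.77, Krt8 at 1.46 and Krt18 at 1.44. Of 19 acute phase genes 5 rose and 0 fell (6 higher and 1 lower adjusted over the list alone, median 0.31), with the metallothionein gene Mt2A at 2.67 and Hp uncalled at 0.12, and of 13 blood vessel genes 1 rose, Vwf at 1.04 (2 higher adjusted over the list alone, median 0.24). Camera called these 7 lists as higher (adjusted p = 3e-09, 2.1e-05, 4.6e-05, 6.1e-05, 0.00038, 0.0067 and 0.04). With an estimated correlation they gave adjusted p = 0.58, 0.2, 0.62, 0.81, 0.68, 0.81 and 0.81. The blood vessel call ended without liver day 10 replicate 1 or day 25 replicate 2 or 3 (0.17, 0.082 and 0.15). The biliary call ended without liver day 25 replicate 1, from rat 7 (median 0.17, adjusted p = 0.062), and the median was 0.55 and 0.64 without replicates 2 and 3.

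Lower lists in the liver were cholesterol synthesis (2 of 14 fell, 5 adjusted over the list alone, median -0.57, adjusted p = 0.00038), with Fdft1 at -1.23 and Fdps at -1.20, interferon response (3 of 21 fell, median -0.41, adjusted p = 0.0014), with Isg15 at -1.03 and Usp18 at -0.98, and bile acid and drug handling (5 of 20 fell, median -0.99, adjusted p = 0.0016), with Fmo1 at -2.53 and Ugt2b1 at -2.35. With an estimated correlation these gave adjusted p = 0.68, 0.68 and 0.81. The interferon median was -0.24 without liver day 25 replicate 1. Hepatocyte genes did not pass in any of 18 cases (median -0.05, adjusted p = 0.71), with Alb at -0.13. The hypoxia list was uncalled (4 rose and 1 fell of 21, adjusted p = 0.065; 0.0444 after quantile normalization and 0.028 and 0.021 without liver day 25 replicates 2 and 3, each calling it), with the haem oxygenase gene Hmox1 at 2.29. Among 22 chemokine genes 1 rose and 3 fell (adjusted p = 0.97), with Cxcl9 at -1.60, and of 15 clock genes 2 fell, Npas2 at -1.62 and Hlf at -1.40 (camera adjusted p = 0.49); Hlf was uncalled with the mean of its probe sets.

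Limma called 1294 of 14218 genes for the liver, 758 higher and 536 lower, and 384 by at least 2-fold (239 higher, 145 lower). It called 557 with only the groups compared. The count was 626 and 633 without liver day 10 replicates 2 and 3 and 738 without liver day 25 replicate 1, from rat 7. Of the 58 named called genes 31 lost their call when 1 of the 6 arrays was left out and 19 without rat 7.

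The change of the tumour-liver difference from day 10 to day 25 was tested as an interaction (n = 3 rats per day). A2m was higher in tumour than in liver by 4.29 at day 10 (SE 0.64, adjusted p = 3.2e-05) and differed by -1.24 at day 25 (SE 0.64, adjusted p = 0.115), a change of -5.53 (SE 0.90, adjusted p = 0.012). The tumour level of A2m was 12.16 ± 0.31 at day 10 and 11.89 ± 1.71 at day 25, and its liver level 7.87 ± 0.89 and 13.13 ± 0.29 (SD). The difference for Il1r2 was 4.25 at day 10 and fell by 2.75 (SE 0.47, adjusted p = 0.012), and that for the granulocyte receptor gene Csf3r went from 3.69 to 2.00 (-1.69, SE 0.37, adjusted p = 0.038), and that for Gpnmb from 3.11 to 1.68 (-1.42, SE 0.32, adjusted p = 0.039). Ch25h (-1.99, SE 0.32), Clec9a (-1.46, SE 0.30) and Ccl17 (-1.07, SE 0.25) were called as well (adjusted p = 0.012, 0.031 and 0.046). With the rat as a block the estimates were equal, Il1r2 and Ch25h were called (adjusted p = 0.043 and 0.038), and A2m, Csf3r, Gpnmb, Clec9a and Ccl17 were not (adjusted p = 0.059, 0.068, 0.068, 0.053 and 0.096). Cndp1 (2.49), Lcn2 (-4.05), Timp1 (-1.97), Cdh11 (-2.07) and Cela1 (2.00) were called with the block alone (adjusted p = 0.012, 0.019, 0.025, 0.019 and 0.025; 0.12, 0.096, 0.061, 0.18 and 0.071 without it). Erbb2 differed by 0.98 without being called (SE 0.53, adjusted p = 0.352).

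For 7 of 19 macrophage genes the tumour-liver difference fell and for 0 it rose (median -1.17, camera adjusted p = 1.3e-14 and, with an estimated correlation, 0.35). All 7 were called as higher in the liver from day 10 to day 25, by 0.71 (Fcer1g) to 1.39 (Lgmn). In the tumour they were uncalled, at -0.61 (C1qa) to -0.17 (Gpnmb). The myofibroblast list was lower too (median -1.22, adjusted p = 2e-07 and, with an estimated correlation, 0.64). In all, camera called 11 lists as lower and 0 as higher, and 0 of these with an estimated correlation. Of the 11, 5 lists, not the macrophage or myofibroblast list, lost the call without 1 array. Limma called 208 of 14218 genes, 53 higher and 155 lower, and 67 with the rat as a block, 34 of which were among the 208. Of the 208 genes, 180 were also called in the liver from day 10 to day 25 and 4 in the tumour. In all, 1294 genes were called in the liver and 8 in the tumour. The interaction also contains both day differences, so these counts do not tell which tissue set the change. The count of 208 ranged from 30 to 63 without tumour day 10 replicates 1, 2 and 3 (55, 33 and 30), tumour day 25 replicates 1 and 2 (40 and 63), liver day 10 replicates 2 and 3 (38 and 49) or liver day 25 replicate 2 (57). It was 93 without liver day 10 replicate 1, 402 without liver day 25 replicate 3 and 412 without the 3 arrays with pancreatic transcripts.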

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

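Of the tests in this part, the level of the hepatocyte list in the lobe was chosen only after the result was seen, as were the medians without rat 7 of whole lists, the lists of male-biased, female-biased and fat synthesis genes and the fits without rat 7. The difference between tumour and liver was itself different at day 10 and day 25, by a test of the change (n = 3 rats per day). It changed for 208 of 14218 genes. Among the genes named for tumour against liver, A2m changed by -5.53 on the log2 scale, Il1r2 by -2.75, Csf3r by -1.69 and Gpnmb by -1.42. With the rat as a block 67 genes were called, and of these 4 genes only Il1r2 kept its call (adjusted p = 0.043). The liver levels of the 4 genes rose between the days (A2m by 5.26 and Il1r2 by 3.67), and their tumour levels were not called.

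Genes of fatty acid synthesis and some male-biased genes were lower in the right liver lobe at day 25 than at day 10. Of 15 fatty acid synthesis genes 9 fell and 0 rose (12 lower adjusted over the list alone, median -1.68, camera adjusted p = 1.3e-10; adjusted p = 0.075 with an estimated correlation), among them the regulator genes Srebf1 (-2.27) and Mlxipl (-1.15), the elongase genes Elovl6 (-2.12) and Elovl5 (-1.93) and the carboxylase genes Acacb (-1.73) and Acaca (-1.28). Of 10 male-biased genes 2 fell and 0 rose (5 lower adjusted over the list alone, median -2.31, adjusted p = 0.0016; adjusted p = 0.5 with an estimated correlation), Slco1a1 (-2.35) and Cyp2d4 (-0.69). The male-biased list shares 2 genes with the bile acid list, and the fatty acid synthesis list 1 gene with the adipocyte list.

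A loss of hepatocytes from the sampled lobe is argued against by the hepatocyte list, whose median change was -0.05 over 18 genes and -0.03 over the 12 that lay more than 1 log2 below the top of the scale, where the lowest was -1.95 and the next -0.17. A turn to the female pattern stays open: the female-biased list had a median of 0.06 with members in both directions (3 rose, 2 fell of 15), among them Cux2 at 1.38, Trim24 at 1.99 and Aox1 at -2.23. Rat 7 as the only source is argued against for the fatty acid synthesis list by its median without rat 7, -1.41 (14 of 15 genes lower, camera adjusted p = 1.2e-09). For the male-biased list the median shrank from -2.31 to -1.29 without rat 7 (9 of 10 lower, camera adjusted p = 0.0069). The mean of that list was 9.85 in liver day 25 replicate 2 and 11.17 in replicate 3, against 11.71 to 11.8 at day 10. Replicate 3 lay within the day 15 range of 10.99 to 11.7. The fall left without rat 7 thus rested mainly on replicate 2, and for the male-biased list the question stays open. In the fits without rat 7, 7 of the 11 called lower genes of both lists were called, which does not decide the question. Of the male-biased genes only Cyp2d4 (-0.69) stayed called. Slco1a1, Acaca, Acsl5 and Tkfc lost the call as the changes shrank, for Slco1a1 and Acsl5 with a wider SE. With all rats they were at -2.35, -1.28, -1.04 and -1.92 (SE 0.66, 0.32, 0.24 and 0.48). Without rat 7 they were at -2.15, -0.90, -0.88 and -1.41 (SE 0.78, 0.29, 0.27 and 0.45, limma adjusted p = 0.11, 0.077, 0.064 and 0.071). Tumour growth and the time since inoculation go together in this design, so a response of the liver to the growing tumour may be a candidate explanation but was not tested.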

How the results depend on the processing

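Of the alternatives below, those without rat 7, without the 3 arrays with pancreatic transcripts, with the hepatocyte score and of lists without 1 array were chosen only after the result was seen. No named gene that was called turned its direction. Without 1 array this was set in advance for genes named by size of change, whose arrays did not overlap between the groups. The larger side of the calls turned in places: at day 10 from 4318 higher and 3988 lower to 3808 and 4068 after quantile normalization, 4184 and 4235 after median centring, 4104 and 4262 with the mean of the probe sets and 6683 and 9255 with every probe set. At day 15 they turned from 4009 and 3355 to 3623 and 4048 after median centring and 6272 and 6875 with every probe set. Over all days they turned from 5229 and 5377 to 3474 and 2290 with the dimmer genes left out, 1808 and 1186 with a minimum of 2-fold, 4701 and 4415 at an adjusted p under 0.01, 5281 and 5194 with the rat as a block, 5145 and 5120 without tumour day 10 replicate 1, 5221 and 5169 without tumour day 25 replicate 3 and 5268 and 5102 without the 3 arrays. Counts for tumour against liver over all days, at days 10, 15 and 25 and for metastasis against liver were 5764, 4742, 4599, 4592 and 4979 with the dimmer genes left out, and 21452, 15938, 13147, 12348 and 14932 with every probe set, which test fewer and more features. With a minimum of 2-fold they were 2994, 3167, 2956, 2816 and 3375. Leaving out an array moved these counts by less than 1.5 times.

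Tumour day 25 against day 10 (8) gave 0 genes with the dimmer genes left out, 0 with only the groups compared and 0 at an adjusted p under 0.01 (1486, 2534 and 2444 at an unadjusted p under 0.05 with limma). It gave 0 with the hepatocyte score (908), 1156 without the 3 arrays, and 0 to 159 without 1 array. Higher and lower calls were 2 and 6, with 1 and 6 after quantile normalization, 1 and 7 after median centring, 5 and 4 without rat 7 and 462 and 694 without the 3 arrays. In the list tests the median turned without tumour day 25 replicate 1 for the acute phase (0.13) and cell cycle lists (-0.02). Tumour day 15 against day 10 (0) gave 0 to 1 and day 25 against day 15 (0) 0 to 7 without 1 array, both highest without tumour day 15 replicate 3; the latter gave 1 with every probe set.

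Metastasis against tumour (48) gave 1 with only the groups compared, 30 at an adjusted p under 0.01, 0 with the rat as a block, 187 without rat 7, 19 without the 3 arrays, 0 with the hepatocyte score (1911 at an unadjusted p under 0.05) and 21 to 220 without 1 array. The hepatocyte score parts these groups by itself, so the fit with it is no check of the calls. The fatty acid oxidation median turned to 0.02 without metastasis replicate 1. The liver (1294) gave 557 with only the groups compared, 405 at an adjusted p under 0.01, 384 with a minimum of 2-fold and 626 to 1651 without 1 array, lowest without liver day 10 replicate 2 and highest without liver day 25 replicate 3. The interaction (208) gave 9 at an adjusted p under 0.01, 130 with a minimum of 2-fold, 402 with the rat as a random block, 67 with the rat as a block, 412 without the 3 arrays and 30 to 402 without 1 array. The causes were not tested.

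Of named called genes 0 of 91 lost the call without 1 array in tumour against liver, 7 of 7 in tumour day 25 against day 10, 2 of 13 in metastasis against tumour and 31 of 58 in the liver. Over the 189 list tests within rats the rat as a block added 21 calls and ended 0; it ended the calls of the 13 genes of metastasis against tumour and, in the interaction, of the genes given there and of P2ry10, Lgmn, Timp2, Ccl21, Vwf and Armc10 (adjusted p = 0.028, 0.012, 0.024, 0.041, 0.047 and 0.046; 0.07, 0.059, 0.064, 0.072, 0.14 and 0.15 with the block). It added those of Cndp1, Lcn2, Timp1, Cdh11 and Cela1 in the interaction. Of tumour against liver over all days it ended no call of a named gene. The signal over background of the arrays limits what can be said of dim genes, and the 3 arrays per group limit the precision.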

Other observations

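Of the tests in this part, those of liver cells in the sampled piece, of liver RNA of the same rat, of array scaling and of intestinal epithelium per array were chosen only after the result was seen, as were the extra gene lists and the dendritic cell list without 1 array. Livers of day 15, which entered no comparison over time, lay between those of days 10 and 25 for several genes but not for all. The mean of the cholesterol synthesis list was 10.43, 9.97 and 10.21 in the day 15 livers. It was 9.57 to 9.76 at day 10 and 8.88 to 9.31 at day 25. Cyp2c11 was at 12.53 ± 0.92 (SD, n = 3) at day 15, with 13.48 at day 10 and 7.94 at day 25, and Obp3 was at 12.15 ± 1.03 at day 15. A2m, the acute phase inhibitor, was at 8.97 ± 0.28 at day 15, against 7.87 and 13.13. Lcn2 differed widely between the 3 livers of day 15, at 8.13, 5.02 and 9.99. In the tumours Cndp1 was at 8.77 at day 10, 9.72 ± 1.23 at day 15 and 12.21 at day 25.

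Liver genes were far lower in metastases than in day 25 tumours. Of the 47 called lower genes 47 had a day 25 liver mean above the tumour mean, as had 50.7% of all genes, and their median levels were 13.41 in liver, 10.46 in tumour and 5.4 in metastasis. Many of them are liver genes, so this count largely restates what they are and is no separate support. The next test took its liver genes from those with a liver mean at least 3 log2 above the metastasis mean. Over the 200 liver genes that differed most between rats, tumour and liver of the same rat deviated together with a mean r of 0.46 (0.08 in rat 4 and 0.28 in rat 8 to 0.65 in rat 6), the highest of all pairings of the rats within days (highest other 0.37; one-sided exact permutation p = 0.0046, the smallest that these pairings can give). The percentiles of the hepatocyte list within the array differed by medians of -30.4, -46.4 and -71.2 in rats 7, 8 and 9. Array scaling keeps the order of genes. RMA had already aligned the distributions of the arrays, so these percentiles restate the fall and are no separate test of scaling. The same-rat correlation paired livers with tumours only, so it does not tell how much liver was in the metastases. It also cannot part liver tissue taken along at sampling from hepatocytes inside the tumour or from differences between rats shared by both tissues. Liver tissue taken along with the tumours, and less with the metastases, stays a candidate for the lower liver genes in metastases. No biological explanation was tested.

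Pancreatic transcripts appeared in day 15 tumour replicate 2, day 25 tumour replicate 3 and metastasis replicate 2. Over 18 further acinar genes these arrays lay above the median of the other tumour and metastasis arrays by 1.48, 2.18 and 4.61, and the other 9 arrays, day 10 tumour replicate 2 among them, differed by -0.11 to 0.43, so pancreatic tissue in the sampled piece is a candidate source. In day 10 tumour replicate 2 Reg3a was at 7.00, Reg1a at 7.59 and Ctrc at 6.67. The other day 10 tumours had 4.25 and 4.44, 5.74 and 5.77, and 5.44 and 5.56. Cela2a (5.19 against 4.55 and 4.61) and Gp2 (5.15 against 4.59 and 4.41) were also higher there. Cuzd1 (4.64 against 4.73 and 4.87) and Prss2 (3.85 against 3.79 and 3.9) were not above both. Spink1 (7.94 against 8.79 and 9.49) and Ptf1a (5.00 against 5.23 and 5.23) were not higher either, but neither tells of pancreas here. Spink1 was at 7.51 to 11.48 in the livers, and Ptf1a at 5.37 in metastasis replicate 2 against 5.55 and 5.2 in the other metastases. Day 10 tumour replicate 2 stayed in the fits without the 3 arrays, so some pancreatic RNA in those fits is not excluded. Intestinal epithelium as the common source is argued against by 0.02 over 21 intestinal genes, the smallest of the 3 arrays. By array the intestinal genes were at 0.02 in the day 15 tumour, 0.68 in the day 25 tumour, which stays open, and 2.64 in metastasis replicate 2, where gut epithelium may have been present as well. The acinar list shares 1 gene and the intestinal list 5 genes with the fixed list of digestive tissue, and no biological explanation was tested.

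The fall of Clec9a and Ccl17 in the tumours led to the hypothesis of fewer dendritic cells at day 25. Of 20 further dendritic cell genes 18 were lower and 2 higher, with a median of -0.63 (camera adjusted p = 1.6e-06; adjusted p = 0.21 with an estimated correlation), among them the antigen presentation genes Ciita (-1.19), RT1-Bb (-0.90) and Cd74 (-0.74) and the regulator gene Irf8 (-1.20). Limma called 0 of them over all genes and 10 adjusted over the list alone. The median was -0.53 without the tumour of rat 7. Ciita, RT1-Bb and Cd74 are also expressed by macrophages and B cells, and the T and NK cell (-0.37) and macrophage (-0.35) lists were lower in the same comparison, so a lower share of dendritic cells may be part of a wider fall of immune cells and stays a hypothesis.

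Other splits of the same arrays into groups of the same sizes were counted. For tumour against liver over all days 1 of 100 splits, the real one, gave 10606 genes or more, the smallest share that these splits can give. The splits were drawn without regard to the pairing by rat, and only 9 part all pairs, too few for a share under 0.05. No conclusion on chance is drawn from them. The highest other split gave 9227, and it exchanged 1 tumour with 1 liver; among the 9 splits that parted all pairs, as the real one did, the highest other gave 0. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real value and the highest other were 8306 and 0 at day 10, 7364 and 0 at day 15, 7124 and 2 at day 25, 8103 and 1 for metastasis against liver, 1294 and 0 for the liver, 8 and 0 for tumour day 25 against day 10 and 208 and 0 for the interaction, each with 1 split as large. They were 0 and 5 for tumour day 15 against day 10 and 0 and 37 for day 25 against day 15, where 10 of 10 splits were as large. For metastasis against tumour 3 of 10 splits gave 48 genes or more. The others gave 897, with the tumour of rat 7 exchanged with metastasis replicate 2, and 736, and the reason was not tested. Both put the tumour and metastasis of rat 7, which correlated with r of 0.993, in the same group. Splits that gave 3 and 0 did so too. The splits with 897 and 736 genes part fewer pairs, and among the 4 splits parting all pairs the highest other gave 0.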
